A study of Mus musculus with 10 samples.

How the data were processed

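The series measured gene expression in whole testes of 10 day old mice. In SCARKO mice the androgen response of Sertoli cells is removed selectively. Sertoli cells are the somatic cells of the seminiferous tubule that nurse the germ cells. The control mice carried the AMH-Cre transgene, per the labels. Each of the 10 arrays held RNA from 1 pool, made from 1 testis of each of 3 littermate mice, and there were 5 pools per group. Per the labels' protocols, control and SCARKO pools of littermates were made as pairs to adjust for litter, and RNA was extracted on columns with DNase treatment, checked for purity and degradation, amplified by in vitro transcription and labelled with biotin.

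The deposited values were Affymetrix signal intensities on a linear scale, 1 per probe set, for 22690 probe sets. MAS5 was named in the submitters' processing notes for 8 of the arrays and no tool was named for the pair of arrays numbered 5; its version and settings are not given in the sources used here. The mean signal after trimming 2% of the values at each end was 100 on all 10 arrays, so the pair numbered 5 was on the same scale as the others. The median signal per array ranged from 36.4 to 37.6. Between 6.69% and 7.92% of the values on an array lay under 1. Detection calls were not used here. An intensity has no counting depth, so the number of arrays, 5 per group, limits the precision.

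Groups and pair numbers were taken from the titles. The descriptions state the opposite genotype for the 8 arrays numbered 1 to 4 and the same genotype for the pair numbered 5. The titles were used throughout, and the direction of pair 5, on which both labels agree, was compared with that of the other 4 pairs. Groups from the descriptions were tried as an alternative.

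Gene names came from the platform annotation, updated through gene identifiers to the symbols of the mouse assembly GRCm38.p6. Of the 22626 probe sets other than 64 array controls, 20380 listed 1 gene, 691 listed several and 1555 listed none and are unnamed here. Identifiers of 29 single-gene probe sets were not found in the gene table and kept their older symbol. No coordinates are given, because the build behind the array design is not given in the sources used here. The targeted gene is not reported here, so the groups rest on the labels alone.

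Values under 1 were set to 1 and log2 was taken, with no further normalization. The 40% of probe sets with the lowest mean log2 value over the 10 arrays were left out, which removed those under a mean log2 value of 4.27 (a signal of 19.3) and kept 13576. Each probe set was fitted with limma 3.58.1 in R 4.3.3, with the pair as a block and the group as the effect, moderated variances with an intensity trend, a two-sided test, and Benjamini-Hochberg adjustment over all kept probe sets. A probe set was called at an adjusted p under 0.05. Log2 fold changes are SCARKO minus control, with standard errors (SE). For statements about genes, each gene was represented by its brightest kept probe set among the 12603 that named 1 gene, which gave 7973 genes. Calls of genes used the adjustment over all kept probe sets.

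The pair numbers come from the titles and the littermate pools from the labels' protocols. Same-numbered pools also deviated together from their group means, with a correlation across probe sets of 0.27, 0.19, 0.19, 0.11 and 0.39 for pairs 1 to 5. The highest correlation with a pool of another number was 0.109 for pair 4, against 0.109 with its own, so pair 4 did not stand out, while pairs 1, 2, 3 and 5 correlated best with their own. The pairing rests on the protocol of littermate pools, and the fit with the pairs as a block was kept as planned.

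Gene lists were written before the data were examined, 19 in all, of which 17 had at least 3 measured members and were tested. The list test was limma's camera with a preset correlation of 0.01 between genes, adjusted over the 17 lists, with an estimated correlation and limma's fry beside it. Camera compares a list with all other genes. The fry test asks whether a list's genes move, on balance, one way, and its mixed form whether they change in either direction; neither compares the list with other genes. The share of X-linked genes among called genes was tested with Fisher's exact test, two-sided. The ratios of 3′ to 5′ signal of the Gapdh and beta-actin control probe sets were compared with an exact sign-flip test within the 5 pairs, which cannot give a p below 0.063.

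The genes named are Rhox5, Eppin and Serpina5, the 12 with the largest fall and the 8 with the largest rise among called genes that moved the same way in all 5 pairs, and up to 3 members of each list with the smallest p. This rule was fixed before the data were examined. Tktl1, Serpinh1, Serpinb6a, Tuba1a, Kitl, Fshr and Gdnf were named after their values were seen, Tktl1 because it was called without pair 4 and the others to complete the called members of their lists, and so were Pcbd1, which was called and rose at least 2-fold but not in every pair, and the next 6 falls and 5 rises in size in the closing section.

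The procedure was tested on simulated data of 13576 probe sets with the residual spread of these arrays, 50 probe sets for each size of change. It recovered 24% of changes of 0.3 on the log2 scale, 58% of changes of 0.5, 94% of changes of 1 and 98% of changes of 2, and 5 of the 142 probe sets called were false. Changes under about 0.5 on the log2 scale were therefore often missed in the simulation. It gave fewer calls than the 704 of the real arrays, so its adjusted threshold was stricter and its shares may understate the recovery there. The simulated noise was drawn independently for each probe set, whereas genes on the real arrays can vary together. The simulated share of false calls therefore need not hold for the real arrays.

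The alternatives were a fit without the block, quantile normalization, centring on the median, no filter and a 60% filter on dim probe sets, 16 added to each value before log2, variances without a trend, array weights, each pair left out in turn, groups from the descriptions, and for the lists the mean of a gene's probe sets and an estimated correlation. A fit without control pool 2 and without the block, list tests without X-linked genes, counts of called list members without pair 2 and list tests with an estimated correlation in each setting were added after the data were seen.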

Results

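Testis gene expression was compared between SCARKO mice and control mice at day 10, with 5 littermate pairs of pools and 1 array per pool. The comparison asks which testicular transcripts depend on androgen action in Sertoli cells at this age. Signals were scaled to the same trimmed mean of 100 on every array. Each pool combined 3 mice, so the spread between arrays is a spread between pools of littermates.

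The clearest change was a loss of known androgen-regulated Sertoli cell transcripts. Rhox5 (Pem), an X-linked homeobox gene and a standard marker of androgen action in Sertoli cells (gene ID 18617), had a signal of 178 ± 61.7 in control pools and 9.48 ± 1.91 in SCARKO pools (mean ± SD, n = 5). Control pools ranged from 86.6 to 241.4 and SCARKO pools from 7.9 to 12.7, a log2 fold change of -4.17 (SE 0.24, adjusted p = 6.1e-06) that was 17.95-fold lower in SCARKO. Eppin, a protease inhibitor of the male tract (gene ID 75526), was 7.999-fold lower, at 342 ± 86.6 against 42.2 ± 8.68 (log2 fold change -3.00, SE 0.15, adjusted p = 5.2e-06). Serpina5, the protein C inhibitor (gene ID 268591), was 2.39-fold lower, at 257 ± 56.3 against 105.5 ± 10.7 (log2 fold change -1.26, SE 0.09, adjusted p = 5.6e-05). All 3 fell in each of the 5 pairs. The SCARKO signal of Rhox5 lay under the signal of 19.3 below which probe sets were treated as dim, so the size of its fall depends on how low values are handled. With 16 added before log2 its log2 fold change was -2.86.

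**Figure D1:**
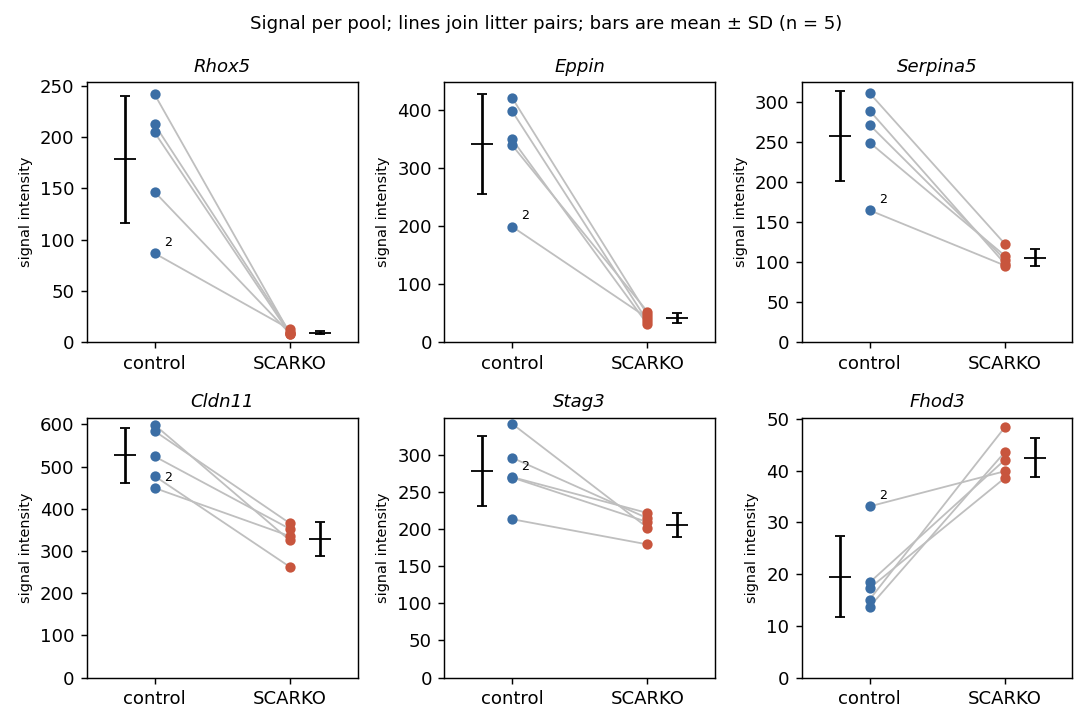
Signal intensity (linear, axes from 0) of 6 genes in the 5 control (blue) and 5 SCARKO (red) pools; lines join littermate pairs, bars are the mean ± SD, and the control pool of pair 2 is marked. Rhox5 lies between 86.6 and 241.4 in control pools and between 7.9 and 12.7 in SCARKO pools, while Fhod3 goes the other way with control pool 2 nearest to the SCARKO pools.

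Beyond these, the largest falls covered a receptor, enzymes and neuronal or secretory proteins. Drd4, a dopamine receptor, fell by 2.38 on the log2 scale (SE 0.13) and Tsx, a testis-specific X-linked gene, fell by 2.35 (SE 0.18). Gpd1, the cytosolic glycerol-3-phosphate dehydrogenase, fell by 1.67 (SE 0.24), the lipid-transfer protein gene Stard10 fell by 1.38 (SE 0.12) and Nags, which makes the activator of the urea cycle, fell by 1.30 (SE 0.15). Lratd1 fell by 1.34, the neuronal tubulin gene Tubb3 fell by 1.23, Pcsk1n, which encodes the precursor of a prohormone convertase inhibitor, fell by 1.19, and Clstn1 fell by 1.13. Adjusted p for these genes lay between 6.1e-06 and 0.0028, and each fell in all 5 pairs. Tsx, Gpd1 and Nags also ended under the dim signal in SCARKO pools. With 16 added before log2 their changes were -1.34, -1.09 and -0.73.

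The rises were smaller. Fhod3, a formin that organizes actin, rose from 19.5 ± 7.81 to 42.5 ± 3.81 (SD, n = 5), a log2 fold change of 1.19 (SE 0.18, adjusted p = 0.0040). The keratin gene Krt18 rose by 0.97 on the log2 scale, the matrix gene Fbln2 by 0.90, Edn1, which encodes endothelin-1, by 0.81, the proteoglycan gene Bcan by 0.78 and the ephrin receptor gene Epha2 by 0.74. Ptges, a prostaglandin E synthase, rose by 0.71 and Cables1 by 0.67. Adjusted p lay between 0.00041 and 0.012, and all 8 rose in every pair. Pcbd1, a pterin dehydratase gene named after its values were seen, rose by 1.03 (SE 0.25, adjusted p = 0.041) with the same direction in 4 of 5 pairs. Control means of Krt18 (15.7), Ptges (18.5) and Pcbd1 (14.7) lay under the dim signal of 19.3 and that of Fhod3 close to it, and with 16 added before log2 their changes were 0.55, 0.42, 0.57 and 0.74. The call of Ptges ended without pair 3 (adjusted p = 0.057) or 5 (0.055), and that of Pcbd1 without pair 1, 3, 4 or 5 (0.081 to 0.15).

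**Figure D2:**
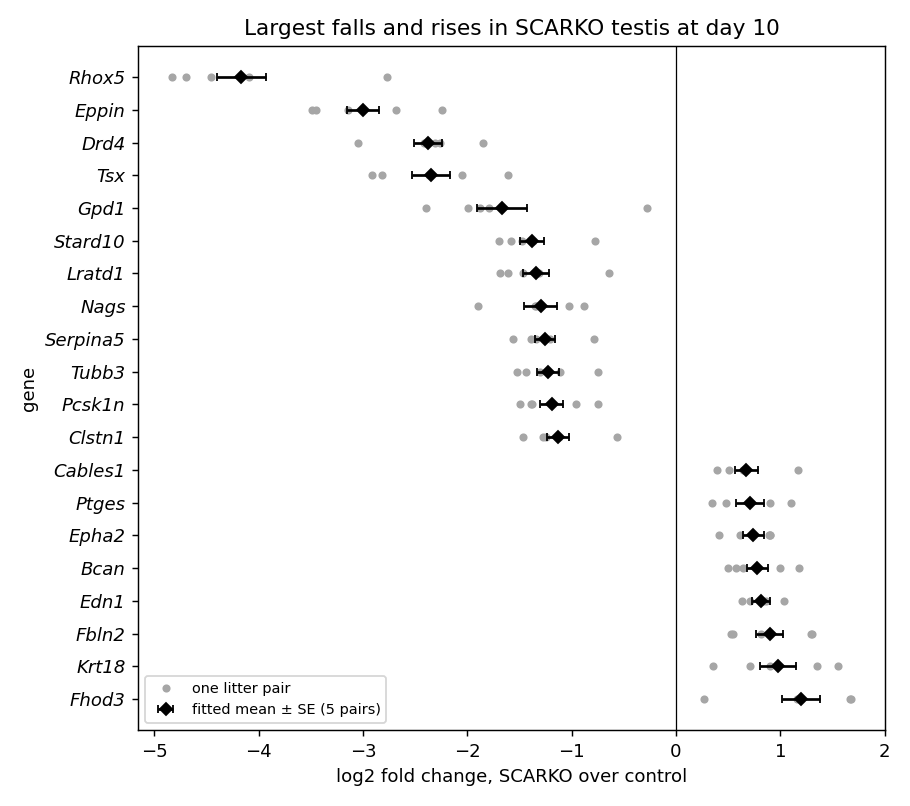
Log2 fold change (SCARKO over control, horizontal axis) of the 12 genes with the largest falls and the 8 with the largest rises among called genes that moved the same way in all 5 pairs; grey points are the 5 littermate pairs, and diamonds with bars are the fitted mean ± SE. Rhox5 fell by 4.17 and the largest rise among them, of Fhod3, was 1.19.

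Across the array, 704 of 13576 probe sets differed between SCARKO and control, 442 lower and 262 higher in SCARKO (62.8% lower). By gene, 281 fell and 173 rose among 7973, with a median absolute log2 fold change of 0.36. Large changes were mostly falls: 15 genes fell and 2 rose at least 2-fold, and 57 fell and 20 rose at least 1.5-fold. The 2-fold count depended on how dim values were handled, with 22 probe sets against 12 without the filter, 10 with the lowest 60% left out and 11 with 16 added before log2. Of the 454 called genes, 437 moved the same way in all 5 pairs, which calls made on these same pairs favour. Among all tested genes 19.7% did so, against 6.25% by chance, a comparison without a test of its own. The number of calls depended on the fit and the pairs, with 404 probe sets called without the littermate block, 38 without the filter on dim probe sets, and between 304 (without pair 3) and 743 (without pair 2) when 1 pair was left out. Without pair 1 the count was 422 and without pair 5 it was 344.

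Titles and descriptions named opposite genotypes for pairs 1 to 4 and the same genotype for pair 5. The log2 ratios of pair 5 correlated with the mean of the other pairs at r = 0.50 (Spearman rho 0.39) across probe sets, which are not independent replicates. Without the filter on dim probe sets it was r = 0.099. Of the 344 probe sets called in pairs 1 to 4 alone, 327 (95.1%) had the same direction in pair 5. Each of the other pairs also correlated positively with the mean of the rest, from r = 0.29 for pair 2 to r = 0.52 for pair 3. With groups from the descriptions for pairs 1 to 4, limma called 0 probe sets, with 611 at an unadjusted p under 0.05, and the log2 fold change of Rhox5 was 2.39 (adjusted p = 0.90). If the descriptions were right for pairs 1 to 4, pair 5 would go the opposite way to them. The shared direction therefore argues against the descriptions there, provided that the labels of pair 5 are right. Every direction given here rests on the titles.

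Among androgen-response genes of Sertoli cells, all 7 measured members fell (7 also when adjusted over the list alone), with a median log2 fold change of -2.35. That median is the value of Tsx, which ended under the dim signal in SCARKO pools, so the size of the median depends on how low values are handled. Rhox5, Eppin, Drd4, Tsx, Gpd1, Tubb3 and Serpina5 made up the group. The list as a whole was lower than other genes by camera (adjusted p = 5.1e-20), a call that was lost at adjusted p = 0.25 with an estimated correlation, although it held without the block (adjusted p = 0.017 with an estimated correlation). Part of this list is known from SCARKO testes, this study included, so its direction is not independent evidence.

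Serine protease inhibitors moved in both directions. Of 15 measured members, Eppin, Serpina5 and Wfdc1 (log2 fold change -0.30) fell, Serpinh1 (0.22), a collagen chaperone, and Serpinb6a (0.19) rose, and 10 did not pass. Adjusted over the list alone, 3 fell and 3 rose. Calls ended for Wfdc1 without pair 3 (adjusted p = 0.056), Serpinh1 without pair 1, 3 or 5 (0.062 to 0.084) and Serpinb6a without pair 2, 3, 4 or 5 (0.053 to 0.12), and for all 3 without the block (0.13, 0.083 and 0.20). Camera gave an adjusted p of 0.42, and the signs differed between the median (0.0047), the mean (-0.23) and the test, which pointed down. The labels' keywords name this class, so the study may have chosen it on these samples.

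Cell junction genes included 3 that fell and none that rose among 25. The Sertoli tight junction gene Cldn11 fell from 527 ± 65.1 to 328 ± 39.96 (SD, n = 5; log2 fold change -0.68, adjusted p = 0.00029), the junctional adhesion molecule gene Jam3 fell by 0.54 and Cdh2, which encodes N-cadherin, by 0.50. Adjusted over the list alone, 4 fell and 2 rose, and camera gave an adjusted p of 0.26. Without pair 2, 4 fell and 1 rose. Of 30 cytoskeletal genes, 4 fell and 1 rose, the same counts as adjusted over the list alone. Tubb3, the microtubule-binding protein gene Map7 (-0.38), Tuba1a (-0.27) and Tmsb4x (-0.18) fell and Krt18 rose, and camera gave an adjusted p of 0.36. Without the block Tmsb4x was not called (adjusted p = 0.086).

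Of 34 genes of the extracellular matrix and basement membrane, 2 fell and 1 rose, or 4 and 4 adjusted over the list alone. Plat, which encodes tissue plasminogen activator, fell from 213 ± 23.3 to 126 ± 16.1 (SD, n = 5; log2 fold change -0.76, adjusted p = 0.00041), Timp2 fell by 0.36 and the laminin gene Lamb1 rose by 0.23. The list median (0.012) and mean (-0.0092) differed in sign, the test pointed up, and camera gave an adjusted p of 0.85. Without pair 2 the list held 4 falls. Calls ended for Timp2 without pair 3 (adjusted p = 0.067) or 5 (0.063), and for Lamb1 without pair 1, 3 or 5 (0.086 to 0.12), and without the block for both (0.18 and 0.11).

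Among 135 measured solute carriers, 10 fell and 4 rose (15 and 5 adjusted over the list alone). The iron transporter gene Slc11a2 fell from 115 ± 16.6 to 65.4 ± 7.53 (SD, n = 5; log2 fold change -0.81, adjusted p = 0.00033), with -0.33 and -0.05 for its 2 other probe sets. Slc25a45 fell by 0.58 and the X-linked adenine nucleotide translocator gene Slc25a5 fell by 0.49. As a list they did not pass (camera adjusted p = 0.15; adjusted p = 0.55 with an estimated correlation), although they passed without pair 2 at 0.047 (adjusted p = 0.26 with an estimated correlation). Of 16 genes of vitamin A metabolism, 2 fell, Aldh1a2 (-0.24, adjusted p = 0.045), which makes retinoic acid, and Aldh1a7 (-0.54, adjusted p = 0.046, lower in 4 of 5 pairs), while Crabp1 had a log2 fold change of 0.21 at an adjusted p of 0.093. Adjusted over the list alone, 2 fell and 1 rose. Its median (0.069), mean (0.019) and test pointed up although both called members fell, and camera gave an adjusted p of 0.49. Both calls were marginal. They ended without the block (adjusted p = 0.38 and 0.16), after quantile normalization (0.051 and 0.052) and without pair 1, 3, 4 or 5 (0.085 to 0.15 and 0.085 to 0.14).

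Cholesterol biosynthesis changed in both directions, with 1 fall and 2 rises among 18 genes, also when adjusted over the list alone. The sterol isomerase gene Ebp, on the X, fell by 0.38, while Fdps rose by 0.34 and Idi1 by 0.26. The other probe set of Idi1 had a log2 fold change of 0.03. Camera gave an adjusted p of 0.18, or 0.033 without X-linked genes, an alternative added after the data were seen. With an estimated correlation neither passed (adjusted p = 0.63, or 0.48 without X-linked genes). Calls ended for Fdps without pair 1, 3 or 4 (adjusted p = 0.088 to 0.10) and for Idi1 without pair 3, 4 or 5 (0.10 to 0.17) and without the block (0.12).

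Sertoli cell markers moved in both directions. Of 21 measured, 3 fell: Nr0b1 (231 ± 37.7 against 126 ± 11.2, SD, n = 5; log2 fold change -0.86, adjusted p = 0.00041), which encodes the nuclear receptor DAX1, Gata1 (-0.50) and the anti-Müllerian hormone receptor gene Amhr2 (-0.43). Another 3 rose: the FSH receptor gene Fshr (0.42, adjusted p = 0.026), the growth factor gene Gdnf (0.39, adjusted p = 0.0496) and Kitl (0.24, adjusted p = 0.015), which encodes stem cell factor. Adjusted over the list alone, 5 fell and 4 rose, and camera gave an adjusted p of 0.49, with a median of 0.020 and a mean of -0.051, the test pointing down. Without pair 2, 4 fell and 1 rose. The calls of the rises were the less secure ones: that of Gdnf ended without any 1 of the 5 pairs (adjusted p = 0.082 to 0.16) and without the block (0.14), that of Fshr without pair 1, 2 or 4 (0.068 to 0.090), and that of Kitl without pair 1 (0.052) or 3 (0.070).

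Of 19 measured genes of meiotic prophase, 3 fell and none rose, and 18 had a negative log2 fold change (median -0.21). As a list they were lower than other genes by camera (adjusted p = 2.2e-06), a call that was lost at adjusted p = 0.55 with an estimated correlation, and by fry they did not pass as moving one way (adjusted p = 0.14). Adjusted over the list alone, 5 fell. The meiotic cohesin gene Stag3 fell from 278 ± 46.7 to 205 ± 16.2 (SD, n = 5; log2 fold change -0.42, adjusted p = 0.0063), the germ cell chaperone gene Hspa2 fell by 0.31 and Tex15 by 0.24. Pairs differed, with list medians of -0.38 and -0.40 in pairs 2 and 3 against -0.05 and -0.04 in pairs 1 and 4, and without pair 2 only 1 member was called. The call of Hspa2 ended without pair 1, 2, 3 or 5 (adjusted p = 0.061 to 0.13) and that of Tex15 without pair 2, 3 or 5 (0.083 to 0.14), and both without the block (0.086 and 0.18).

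Of 19 spermatogonial genes, limma called 0, with 3 at an unadjusted p under 0.05, and none was called when adjusted over the list alone. Among all 7973 genes, 454 were called and 1729 had an unadjusted p under 0.05. Log2 fold changes were 0.13 for Uchl1, 0.24 for Dnd1 and -0.29 for Tex101, at adjusted p of 0.083, 0.18 and 0.20. The list median was 0.057 (camera adjusted p = 0.18). Without pair 4, Tktl1, a transketolase-like gene named after its values were seen, was called (log2 fold change -0.22, adjusted p = 0.048), against -0.12 and 0.40 with all pairs.

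**Figure D3:**
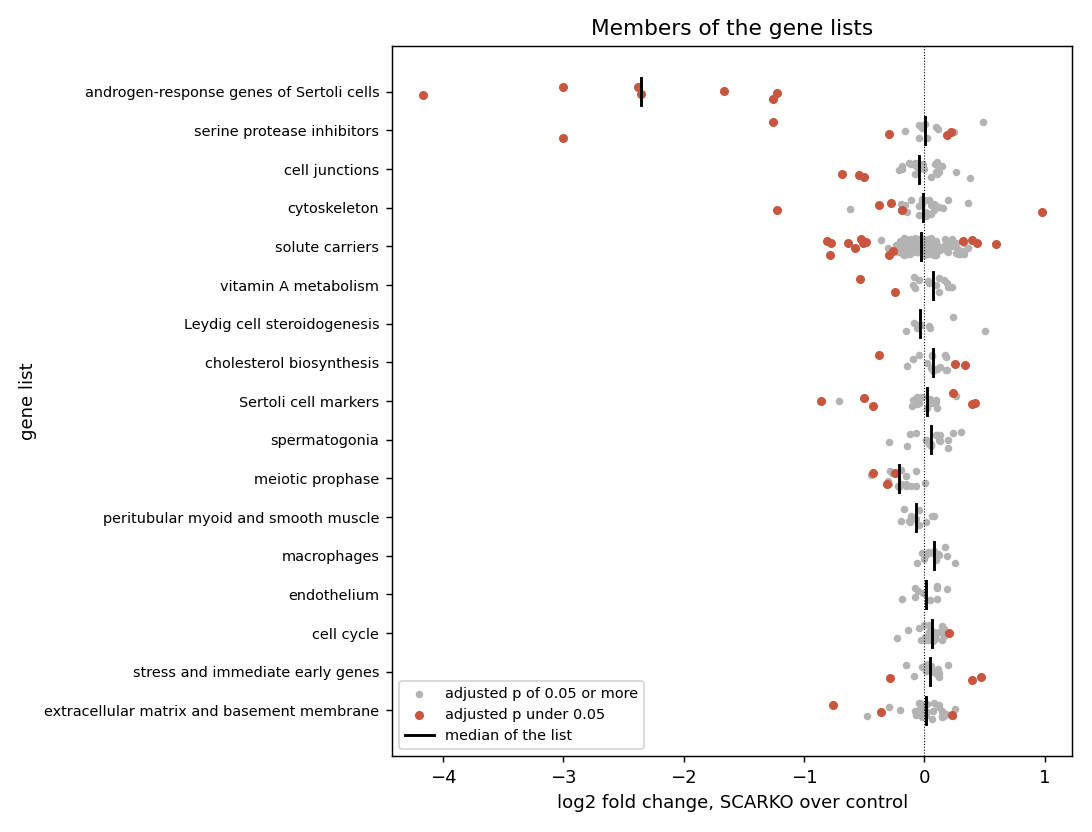
Log2 fold change (SCARKO over control, horizontal axis) of each measured member of the 17 tested gene lists (vertical axis); red points had an adjusted p under 0.05, grey points did not, and black bars are list medians. The androgen-response genes (median -2.35, the value of Tsx, which was dim in SCARKO pools) and the meiotic prophase genes (median -0.21) lie to the left, while the spermatogonial median is 0.057.

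Among markers of the other testicular cell types, no member passed with all 5 pairs, while 1 myoid gene, Tpm2, passed without pair 2 (log2 fold change -0.19, adjusted p = 0.047). Limma called 0 of 10 genes of Leydig cell steroidogenesis, 0 of 11 of peritubular myoid cells and smooth muscle, 0 of 13 of macrophages and 0 of 10 of endothelium, also when adjusted over each list alone, with 2, 2, 2 and 1 at an unadjusted p under 0.05. In the same order, list medians were -0.040, -0.067, 0.082 and 0.017, and camera gave adjusted p of 0.87, 0.17, 0.29 and 0.87. Over all 7973 genes, 454 were called and 1729 had an unadjusted p under 0.05. Lists this short would hold few or no calls at that rate, so their absence does not show that these cell types were unchanged. Without pair 3 the myoid list passed at 0.021 (adjusted p = 0.56 with an estimated correlation). The Leydig list's mean (0.039) and test pointed up, against its median. The smallest p in these lists belonged to the steroidogenic enzyme gene Hsd17b3 (log2 fold change 0.50, adjusted p = 0.11), the myosin kinase gene Mylk (-0.17, 0.091), C1qa (0.17, 0.20) and Sox18 (0.19, 0.18). Next in these lists, log2 fold changes were 0.24 for Akr1c14, -0.09 for Thbs2, -0.13 for Tpm2, whose other probe set pointed the other way, and -0.11 for Myh11. They were 0.25 for C1qc, 0.12 for Lyz2, -0.19 for Cdh5 and 0.10 for Eng, none past the threshold. No erythroid gene reached the kept signals, the highest mean log2 value of their probe sets over the 10 arrays being 4.24, under the 4.27 that was required. Of the markers of epididymis and fat, Lpl, the lipoprotein lipase gene, was the 1 measured and rose by 0.51 (adjusted p = 0.0020). No other of these markers on the array reached the kept signals.

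Of 26 cell cycle genes, 22 had a positive log2 fold change, and Ccna2, the cyclin A2 gene, rose by 0.20 as the 1 called member, also when adjusted over the list alone. Ccnb2 (0.16) and Bub1b (0.18) did not pass. The call of Ccna2 ended without pair 3, 4 or 5 (adjusted p = 0.11 to 0.13). Camera gave an adjusted p of 0.12, and 0.016 without pair 2. With an estimated correlation the list did not pass, at adjusted p = 0.64, or 0.54 without pair 2. Of 18 stress and immediate early genes, Jun (0.47) and Ier3 (0.40) rose and the heat shock gene Hspa1b (-0.29) fell, or 4 and 1 adjusted over the list alone, with a camera adjusted p of 0.27. The call of Ier3 ended without any 1 of the 5 pairs (adjusted p = 0.053 to 0.16). Signs of RNA integrity were close between the groups. The log2 ratio of 3′ to 5′ signal was -0.67 ± 0.03 in control and -0.65 ± 0.04 in SCARKO pools for Gapdh (exact sign-flip p = 0.25) and 0.31 ± 0.05 against 0.32 ± 0.07 for beta-actin (exact p = 0.75; SD, n = 5), in a test that cannot go below 0.063.

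By fry, 3 of the 17 lists moved one way on balance at an adjusted p under 0.05. These were the androgen-response genes (0.0067), the serine protease inhibitors (0.045) and the stress genes (0.045). The protease inhibitor list shares Eppin and Serpina5 with the androgen-response list, so its result is not separate evidence. Of its 15 measured members, 7 were lower and 8 higher, and fry was not run without the shared genes. In fry's mixed form, for change in either direction, 12 of the 17 passed. Among them were the Sertoli cell markers (7.0e-05), the androgen-response genes (0.00071), the spermatogonial genes (0.033) and the meiotic prophase genes (0.030). The 5 that did not were the lists of Leydig cells (0.64), myoid cells (0.32), macrophages (0.50), endothelium (0.64) and the cell cycle (0.080).

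X-linked genes were over-represented among called genes. Of 269 X-linked genes tested, 34 (12.6%) were called, against 420 of 7696 others (5.46%), an odds ratio of 2.51 (95% interval 1.67 to 3.66, Fisher's exact p = 1.1e-05, adjusted 1.6e-05 over 3 tests). Among them 26 X-linked genes were lower (odds ratio 3.12, interval 1.96 to 4.79, exact p = 2.6e-06, adjusted 7.8e-06), among them Rhox5, Tsx, Pcsk1n, Nr0b1, Slc25a5 and Gata1. For the 8 that rose the odds ratio was 1.40 (interval 0.588 to 2.86, exact p = 0.39, adjusted 0.39). The share of X-linked genes did not pass as different between called falls and called rises (odds ratio 2.10, interval 0.896 to 5.50, exact p = 0.097, a test chosen after the data were seen). Without the filter on dim probe sets the X-linked share of called genes was 6.90% instead of 7.49% (exact p = 0.24). These exact tests treat genes as independent, although all were measured on the same pools. Their p and intervals therefore do not measure the spread between pools.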

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

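On the log2 scale, each value here lay so far from the rest of its group of 5 that its gap to the nearest one, over the range of the group, exceeded the 95% critical value of a test for a single stray value (Dixon). Of 158 group values tested, 13 did so, against 7.9 that chance alone gives, so several of them are what chance would produce. On the signals without log2, which are printed here, 9 of the 13 did so, and those of Eppin, Gpd1, Clstn1 and Slc11a2 did not. The tests of a mixed pool and of an exchange in pair 2 were chosen after the result was seen, and the test of compressed signals before. The condition that a mixed pool should shift both directions alike was made stricter, to overlapping intervals, after the values were seen.

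Control pool 2 held 5 of the 13 values, and each was the lowest control for a gene that fell in SCARKO. Its signals were 199.5 for Eppin (other control pools 340.1 to 421.8), 23.2 for Gpd1 (52.6 to 71.7), 74.1 for Stard10 (119.7 to 132.7), 114.8 for Clstn1 (203.4 to 255.6) and 753 for Slc25a5 (912.9 to 950.4). It was the lowest control pool for 6 of the 7 androgen-response genes, its signals lying from 0.339 to 0.849 of the way from the other control pools to the SCARKO pools (median 0.53).

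Genes called in the other 4 pairs, with a log2 change of at least 0.5, placed control pool 2 between the groups. The median gene lower in SCARKO lay 0.579 of the way to the SCARKO level (95% bootstrap interval 0.471 to 0.640, 117 genes), and the median gene higher in SCARKO 0.368 (0.320 to 0.454, 52 genes). An exchange within pair 2 was argued against by SCARKO pool 2, which lay 0.027 of the way to control, and compressed signals by the slope of 0.998 of its array on the other control pools, inside their range of 0.992 to 0.9997. SCARKO tissue in this pool may account for part of the shift, but cannot be told apart from ordinary differences between control pools. A single share of mixed tissue would move both directions alike, and the intervals did not overlap. Those intervals resample genes, which vary together within a pool, so they cannot decide whether both directions moved alike. For genes lower in SCARKO, control pools 1, 3, 4 and 5, held out the same way, lay at 0.197, -0.428, -0.022 and -0.109. The controls they were compared with included pool 2. Litters are part of the design, and a difference of the litter behind pair 2 was not tested.

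Among other genes, Lyz2 had a signal of 72.5 in control pool 1 (other control pools 103.6 to 116.1), and Slc11a2 had 52.5 in SCARKO pool 2 (65.1 to 70.8). In SCARKO pool 1, Fdps had 476.6 (385.6 to 398.7) and Cdh5 had 19.8 (24.4 to 26). The 18S ribosomal control probe sets were bright on both arrays of pair 5. The middle probe set read 954.6 in control pool 5 (others 21.3 to 57.8) and 316.1 in SCARKO pool 5 (17.4 to 30.7). In SCARKO pool 5 the 3′ probe set read 906.4 (29.4 to 50.7) and the 5′ probe set 205.5 (19.7 to 24.5). Control pool 5 was brighter still, at 1248.2 for the 3′ probe set (29.3 to 120.7) and 842.7 for the 5′ probe set (19.1 to 103.3), although these gaps did not exceed the critical value on the log2 scale.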

How the results depend on the processing

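The fit without the littermate block called 404 probe sets (283 lower and 121 higher, 70.0% lower) instead of 704 (442 and 262, 62.8%). It also turned the sign of the matrix list's test (adjusted p = 0.99), with the list median still 0.012, and ended the calls of 12 named genes. Without the filter on dim probe sets 38 were called (31 and 7, 81.6%). The moderated fit then borrowed less, with 1.73 prior degrees of freedom instead of 7.34, and 52 of 65 called named genes lost their call. Variances without a trend gave 321 (212 and 109, 66.0%). The share lower was 65.2% after quantile normalization and 60.2% after centring on the median. Leaving out 1 pair gave from 304 to 743 probe sets, 213 to 485 lower, 91 to 258 higher and 65.3% to 70.1% lower. The fit without control pool 2 and without the block, chosen after seeing the data, gave 166 higher and 69.4% lower. At least 2-fold changes numbered 22, or 12 without the filter, 10 with the lowest 60% left out and 11 with 16 added. The correlation of pair 5 with the other pairs was 0.099 without the filter and between 0.49 and 0.57 in the other settings. The X-linked share of called genes was 6.90% without the filter (exact p = 0.24), and passed in the other settings that called any gene. Causes were not tested unless stated.

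Rhox5 fell in every setting that kept the titles, from -2.86 to -4.52; with the lowest 60% left out it was not among the probe sets tested. The 65 other called named genes kept their direction in all 890 repeats that kept the titles and lost their call in 173. Of those losses, 52 came without the filter, 23 without a trend and 20 without pair 3. None of the 260 repeats of the 19 uncalled named genes turned, and 4 passed. The block, the filters and the variance trend leave a fold change as it was, so those settings cannot turn a direction. Leaving out a pair cannot turn a gene that moved alike in every pair. Among the called named genes, all but Pcbd1 and Aldh1a7 did so. The kept directions of called genes were therefore mostly fixed beforehand and are no test of robustness, unlike the lost calls.

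With an estimated correlation the androgen-response list gave an adjusted p of 0.25 and the meiotic prophase list 0.55. Solute carriers passed with the lowest 60% left out (0.00047) and without control pool 2 and the block (0.033). Cholesterol biosynthesis passed without X-linked genes (0.033). The cell cycle list passed without the filter (0.031) and without control pool 2 and the block (0.0089). The sign of the test, none of these past the threshold, turned for the Leydig list with the lowest 60% left out (0.74), the Sertoli markers without X-linked genes (0.90), endothelium without the filter (0.91) and the matrix list without control pool 2 and the block (0.19). The matrix list had already turned without the block alone. Those calls used the preset correlation. With an estimated one, tried after seeing the data, adjusted p was 0.35 and 0.13 for the solute carriers, 0.48 for cholesterol biosynthesis, and 0.65 and 0.53 for the cell cycle. Of 42 list tests that passed with the preset correlation and the titles, 2 passed with an estimated one, both of the androgen-response list: without the block (0.017) and without control pool 2 and the block (0.0042). With 1 pair left out, the lists whose test turned sign or passed had adjusted p from 0.047 to 0.33 (solute carriers), 0.23 to 0.98 (Leydig), 0.021 to 0.50 (myoid), 0.66 to 0.88 (endothelium), 0.016 to 0.60 (cell cycle) and 0.42 to 0.88 (matrix). Called members without pair 2, counted after seeing the data, were 7 of 7 androgen-response genes and 1 of 19 meiotic genes. In the serine protease inhibitor and stress lists 1 member each rose instead of 2, and in the vitamin A list 1 rose instead of 0. Junction genes gave 4 falls and 1 rise instead of 3 and 0, solute carriers 12 falls instead of 10, matrix genes 4 instead of 2, Sertoli markers 4 falls and 1 rise instead of 3 and 3, and myoid genes 1 fall instead of 0. The other lists kept their counts.

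With groups from the descriptions, limma called 0 probe sets (0 lower, 0 higher, 0 at 2-fold) and 611 at an unadjusted p under 0.05. Directions then turn by construction in 4 of 5 pairs. Rhox5 was 2.39. List tests turned with adjusted p of 0.00018 (androgen response), 0.64 (junctions, vitamin A and endothelium), 0.98 (cytoskeleton), 0.61 (solute carriers), 0.033 (Leydig, myoid and cell cycle), 0.52 (cholesterol), 0.9987 (Sertoli markers), 0.55 (spermatogonia), 2.6e-06 (meiotic prophase), 0.073 (macrophages and stress) and 0.28 (matrix). None passed with an estimated correlation, the lists that had passed all giving 0.70. Log2 fold changes that turned positive were Eppin 1.604, Serpina5 0.63, Drd4 1.16, Tsx 1.22, Gpd1 0.71, Stard10 0.70, Lratd1 0.82, Nags 0.54, Tubb3 0.62, Pcsk1n 0.59, Clstn1 0.69, Wfdc1 0.17, Cldn11 0.33, Jam3 0.24, Cdh2 0.22, Map7 0.19, Tmsb4x 0.11, Slc11a2 0.40, Slc25a45 0.33, Slc25a5 0.25, Aldh1a2 0.18, Aldh1a7 0.32, Ebp 0.20, Nr0b1 0.52, Amhr2 0.26, Gata1 0.14, Tex101 0.19, Stag3 0.32, Hspa2 0.19, Tex15 0.11, Mylk 0.13, Tpm2 0.070, Myh11 0.053, Cdh5 0.12, Hspa1b 0.12, Plat 0.35, Timp2 0.17, Tuba1a 0.11, Tpd52l1 0.51, Cdo1 0.73, Hopx 0.60, Cyp2s1 0.49, Notch1 0.43, Lpar3 0.29. Those that turned negative were Fhod3 -0.72, Pcbd1 -0.56, Krt18 -0.35, Fbln2 -0.38, Edn1 -0.48, Bcan -0.31, Epha2 -0.39, Ptges -0.35, Cables1 -0.21, Crabp1 -0.090, Hsd17b3 -0.18, Fdps -0.31, Idi1 -0.099, Uchl1 -0.032, Dnd1 -0.20, C1qa -0.11, C1qc -0.24, Lyz2 -0.13, Sox18 -0.057, Eng -0.21, Lpl -0.32, Ccna2 -0.092, Ccnb2 -0.069, Bub1b -0.11, Jun -0.37, Ier3 -0.35, Lamb1 -0.12, Serpinb6a -0.12, Serpinh1 -0.13, Fshr -0.33, Gdnf -0.20, Kitl -0.15, Mapk13 -0.48, Rnf123 -0.35, F3 -0.28, Lfng -0.60, Mmp23 -0.38.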

Other observations

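Just under the largest changes, 6 further genes fell by 1.88-fold to 2.13-fold and 5 rose by 1.53-fold to 1.59-fold. Tpd52l1 fell from 213 ± 42.7 to 99.0 ± 11.3 (SD, n = 5; log2 fold change -1.09, adjusted p = 0.00014), Cdo1, the cysteine dioxygenase gene, fell by 1.09, and Hopx, a homeodomain-only gene, fell by 1.06, its other probe set by 1.08. Cyp2s1, a cytochrome P450 gene, fell by 0.96, and the lysophosphatidic acid receptor gene Lpar3 fell by 0.91. Notch1 fell by 0.91, with -0.14 for its other probe set, and Lfng, which encodes a glycosyltransferase that modifies Notch receptors, rose by 0.63. The stress kinase gene Mapk13 rose by 0.67, Rnf123 by 0.65, F3, which encodes tissue factor, by 0.64 and Mmp23 by 0.62, its other probe set by 0.61. Each moved the same way in all 5 pairs, with adjusted p between 5.6e-05 and 0.030. Calls of 3 of the rises ended when 1 pair was left out, namely Lfng without pair 1, 3 or 4 (adjusted p = 0.076 to 0.089), Rnf123 without pair 2, 3, 4 or 5 (0.058 to 0.095) and Mmp23 without pair 3, 4 or 5 (0.054 to 0.080). The control mean of Rnf123 (18.2) lay under the dim signal of 19.3, and with 16 added before log2 its change was 0.37.

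The tests of the spermatogonial genes and of directions shuffled among called genes were chosen after the result was seen; the tests of probe mismatches, of single pairs, of splits and of neighbouring genes were chosen before.

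X-linked genes were called more often than others, also without the androgen-response list (odds ratio 2.39, interval 1.57 to 3.52, with genes treated as independent). Only 11 of the 34 called X-linked genes had other kept probe sets. For these, a sequence variant under single probes was argued against, since the others mostly went the same way for 10 of 11 (90.9%, exact binomial interval 58.7% to 99.8%). The remaining genes, among them Rhox5, Tsx and Nr0b1, had no other kept probe set and could not be tested. Whether the groups differ in the strain origin of the X chromosome was not tested here and stays open beside an effect of the genotype, which the design names.

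The meiotic prophase list was lower than other genes by camera, a call lost at adjusted p = 0.55 with an estimated correlation, and 3 of its 19 members passed. A lower share of all germ cells was argued against by the spermatogonial median of 0.057 (95% bootstrap interval over genes 0.017 to 0.129), against a meiotic median of -0.21 (-0.29 to -0.16), and the spermatogonial median lay above the meiotic one in 5 of 5 pairs (mean difference 0.27, exact sign-flip p = 0.063, the smallest that 5 pairs can give). These intervals resample genes and do not measure the spread between pools. A single littermate pair was argued against by the list's adjusted p, at most 0.0017 when 1 pair was left out, although that test presets the correlation between genes and none of these fits passed with an estimated one (adjusted p = 0.54 to 0.71). The meiotic genes also varied between pools of 1 group, with median deviations from -0.15 to 0.43 on the log2 scale among control pools and from -0.40 to 0.05 among SCARKO pools. Whether these genes fell as a list beyond the spread between pools therefore stays open. If they did, signals of whole testes do not separate fewer cells in meiotic prophase from less of these transcripts per cell.

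In 100 splits of the 10 arrays into groups of 5, fitted without the block, 1 split, the real one, gave as many calls. It called 404 probe sets, against at most 16 in the others. Chance is thus an unlikely source of that count, though not excluded. This holds for the fit that ignores the pairs, among splits that ignore them too. Within the pairs there are 16 splits, too few for a share under 0.05. The real split gave 704 probe sets there and the highest other 1, and 1 of the 16 reached the real count.

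Genes that follow each other on a chromosome, in the GRCm38.p6 order of the measured genes, were more often both called in the same direction than by chance. Genes that were not measured can lie between them. The pairs included Gstm2 with Gstm1, Gsta4 with Gsta2 and pairs on the X, and no test was run without these. There were 25 such neighbouring pairs, against a median of 14 in 10000 shuffles of the calls within each chromosome (one-sided permutation p = 0.0063), and 4 pairs called in opposite directions, against a median of 12. With the called genes kept in place and only their directions shuffled, the median was 16 pairs in the same direction (one-sided permutation p = 0.00070).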
